A study of Homo sapiens with 6 samples.

How the data were processed

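The data are 6 one-colour Agilent Human Gene Expression 4x44K v2 arrays hybridised with Cy3-labelled total RNA, 1 array for each of 6 groups (CAL27 and SCC9, each as control, shRNA2 and shRNA5). Per the file headers, spots were read with Agilent Feature Extraction 11.0.1.1, which the submitters' processing notes also name, and the deposited files give each spot's intensity as a processed signal, a median signal and a local background together with detection flags. Per the labels, the authors quantile normalized the raw data, kept detected genes and filtered by p-value or FDR. The authors' deposited value table holds log2 values: each of its 6 columns has a median of 6.02, correlates at r = 0.99 with the scanner values of its own array and lower with every other array, and differs from them by a median of 0.014 to 0.11, so its scale is settled, and the detection floor applied to it stays unknown.

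The main values were computed from the scanner files. Control spots (1377) were left out, the processed signal was taken to log2, quantile normalized over the 6 arrays, and the spots of a probe were averaged without spots flagged as non-uniform or population outliers. Probes were named by matching their unversioned RefSeq accession to a table of RefSeq genes of assembly GRCh38.p14, while the array files name build hg19, so that the table served for names, gene order and gene length, and no coordinates are given. Of 34127 probes, 25771 (75.5%) matched a symbol, and the others kept the name in the files. A gene with several probes (5284 genes) was represented by its brightest probe, which can be a probe that moves differently from the gene's other probes. Where probes of a gene named for a comparison of arrays, or as a neighbour of LINC01011, went different ways, this is stated. For values given for members of the gene lists, agreement between probes was not checked. Genes well above background on at least 2 of the 6 arrays were tested, 22415 in all, of which 16757 had a symbol and 18429 were above background on all 6. XIST and Y-linked genes were left out, and some genes are not reported. For a gene not above background in one arm or line, a lower bound is given: the mean of normalized log2 values of the bright arrays against, per dim array, the higher of the probe's own value and the lowest value among probes well above background.

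Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and version 1.17.8 of data.table, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparison of hairpins with controls had terms for arm and cell line (3 residual degrees of freedom), and its line term gave the comparison of the lines. Effects within each line and their difference came from a fit with 1 mean per line and arm, and single hairpins from a fit with line and construct, both with 2 residual degrees of freedom. No label says that arrays came from separate cultures, so no p-value measures the spread over cultures. In the fit with arm and line, p-values measure the spread over hairpins and lines. With 1 mean per line and arm they measure only that between the 2 hairpins of a line. With line and construct they measure how far the differences between constructs vary between the lines. The 35 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; the median of each list in each hairpin array was placed among 10000 random lists matched on mean expression in 20 bins. The rule for named genes took, among genes with a symbol above background on all 6 arrays, the 12 per direction with the largest change past the threshold and of 1 sign in all 4 hairpin arrays, up to 3 per direction below background in one arm, 5 per direction within each line by the smaller hairpin difference, 4 per direction by smallest p for the difference between lines and the single hairpins, 10 per direction and up to 4 below background in one line for SCC9 against CAL27, members of each list past the threshold or with the largest change, and the 5 genes on each side of LINC01011. BRCA1 is a member of the crosslink repair list.

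Arrays that share a scan identifier were taken as 1 slide, with 4 arrays on slide 1 and 2 on slide 2. The alternatives were the 75th percentile shift, no filter and a filter on all 6 arrays, the authors' deposited table, the mean over probes, eBayes with trend and robust settings, slide as a block, no cell line or arm term, and leaving out each array. Chosen after seeing the data were normexp with an offset of 50 on the median signals, removal of each array's trend with gene length, and the CAL27 arrays alone. The procedure was tested on simulated data with 200 changed genes among 22415. Noise was drawn independently for each gene and array, and far fewer genes changed than passed in the real arrays. A lone control array that deviates as a whole could therefore give no false calls here, and the rates below do not cover that case. For hairpins against controls it recovered 36% of changes of 2 and 80% of changes of 4 on the log2 scale, with 7 unchanged genes called. For shRNA2 and shRNA5 against control it recovered 28% and 26% of changes of 4, and for the difference between lines 44%.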

Results

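Gene expression was measured in CAL27 and SCC9, established cell lines of human tongue squamous cell carcinoma, after LINC01011 had been targeted by short hairpin RNAs. LINC01011 is a long noncoding RNA also known as CISAL. Each line was represented by a control and by stable transductants of 2 hairpins, shRNA2 and shRNA5, which gave 6 groups of 1 array each. Per the labels, cells were exposed for 24 h to cisplatin, a drug that forms bulky platinum adducts and crosslinks in DNA, at its IC50; the dose itself was not given, and the labels state the treatment in the same words for every sample. With 1 array per group no group had a replicate of its own, so no test below rests on the spread between cultures, and the number of arrays limits precision. The test of hairpins against controls rests on the spread between hairpins and cell lines. Tests within a line, and of the difference between lines, rest only on the spread between the 2 hairpins, pooled over both lines. They hold no spread between control arrays. Of the 43118 spots that carry a gene probe, 31999 on the SCC9 control array (74.2%) to 34347 on the SCC9 shRNA2 array (79.7%) were well above background, and no spot was saturated. The control arrays were dimmer than the hairpin arrays before normalization. The median processed signal was 83.6 in the CAL27 control against 123 and 109 in the CAL27 shRNA2 and shRNA5 arrays, and 45.4 in the SCC9 control against 111 and 115 in the SCC9 shRNA2 and shRNA5 arrays. After normalization, 22415 genes could be tested. Across those genes the 2 hairpin arrays correlated at r = 0.992 in CAL27 and at r = 0.982 in SCC9. The CAL27 control correlated with the CAL27 hairpin arrays at r = 0.951 and r = 0.942, and the SCC9 control, which stood apart most, correlated with the SCC9 hairpin arrays at r = 0.845 and r = 0.830. The SCC9 control was closer to the CAL27 control (r = 0.886) than to the hairpin arrays of its own line. The SCC9 hairpin arrays were likewise closer to the CAL27 hairpin arrays (r = 0.920 to r = 0.934) than to the SCC9 control.

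The labels do not state how far the hairpins lowered their target, and no array probe was matched to LINC01011 by accession, so its level was not measured here. Of the 5 genes on each side of LINC01011 in the RefSeq gene order, 4 were tested. SERPINB6 and SERPINB9, which encode intracellular protease inhibitors, had log2 differences between hairpin and control arrays of 0.31 ± 0.22 (SE, adjusted p = 0.32, with 1 of 2 SERPINB6 probes higher) and 1.02 ± 0.64 (adjusted p = 0.26). On the other side, NQO2, a quinone reductase, differed by -0.26 ± 0.33 (adjusted p = 0.57) and RIPK1, a kinase of death receptor signalling, by -0.32 ± 0.25 (adjusted p = 0.35). None of the 4 passed this test of a change shared by both lines. For 2 of them the fitted value averages opposite directions. SERPINB9 had differences of -0.23 and -0.50 in CAL27 shRNA2 and shRNA5 but 2.53 and 2.29 in SCC9 shRNA2 and shRNA5. NQO2 had 0.40 and 0.14 in CAL27 and -0.58 and -0.98 in SCC9, in the same order of hairpins.

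The first comparison asked which transcripts differed between the 4 hairpin arrays and the 2 control arrays in the same direction in both lines. The lists of mitosis, DNA replication, crosslink repair, interferon-stimulated, hypoxia and glycolysis and basal squamous genes were among 15 lists higher in the hairpin arrays (camera, preset correlation). The immediate early, keratinocyte differentiation and ribosome biogenesis lists were lower. No list passed with a correlation estimated from the 6 arrays, where the smallest adjusted p = 0.52 with an estimated correlation. In all, 2657 genes were higher and 3049 were lower (limma, adjusted p under 0.05), 25.5% of the genes tested, and 2558 and 2859 of them differed by at least 2-fold. All 5706 had the same sign in each of the 4 differences between a hairpin array and the control of its line. The test uses these same differences and favours genes with a common sign, so this is no added evidence. Of all genes tested, 61.0% had 1 sign in all 4 differences, against 22% of simulated unchanged genes. The simulation drew independent noise of equal size for every array. In the real arrays the 2 differences of a line had the same sign for 88.1% (CAL27) and 92.1% (SCC9) of genes, against 66.5% and 66.8% when simulated. A lone control that deviates as a whole would also raise this agreement, and for that case 22% is too low a reference. The median gene was itself shifted by -0.23 on the log2 scale, so that a change near this value is no change relative to the other genes.

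Among genes well above background on all 6 arrays, the largest increases shared by both lines were those of FUT8, the enzyme of core fucosylation, with a log2 change of 6.16 ± 0.95 (SE, adjusted p = 0.015), and HEG1, a membrane mucin of cell junctions, with 5.95 ± 0.60 (adjusted p = 0.011). VAV3, a guanine nucleotide exchange factor, rose by 5.61 ± 0.93 and NAV2, a cytoskeletal navigator protein, by 5.57 ± 0.35. IGF1R, the receptor of insulin-like growth factor, rose by 5.38 ± 0.88 and the receptor phosphatase gene PTPRK by 5.34 ± 1.14, though only 2 of its 3 probes above background rose. Averaged over probes, PTPRK had 2.09 and did not pass (adjusted p = 0.062), and PPP1R12B had 1.95 (adjusted p = 0.015). Without the filter on dim probes neither passed (adjusted p = 0.054 and 0.051). The others of the 12 were TRERF1 (5.41), DRC11 (5.38), HOXC4 (5.38), PPP1R12B (5.33, with 3 of 4 probes rising), SH3PXD2A (5.29) and SRGAP2 (5.28). With slide as a block the log2 changes stayed of this size, from 5.04 to 5.99 in the 8 genes named next, but FUT8, SH3PXD2A and SRGAP2 (adjusted p = 0.052 each), VAV3 (0.056), TRERF1 (0.055), IGF1R (0.055), PTPRK (0.082) and PPP1R12B (0.078) did not pass. The sizes and their order depend on the background correction: with normexp all 12 passed, from 2.82 for DRC11 to 5.19 for HEG1, with FUT8 at 3.70, NAV2 at 3.87 and HOXC4 at 3.15. Averaged over probes TRERF1 had 4.22 and SH3PXD2A 3.45. SNAI1, a transcription factor of epithelial-mesenchymal transition, had the largest decrease among these genes, with a log2 change of -7.25 ± 0.39 (adjusted p = 0.0081) and differences from -6.46 to -8.14 in the 4 hairpin arrays. With normexp it had -5.45, next to LCE3D with -5.55, and the 12 leading decreases ran to -2.68 for RAD21-AS1. Several of the strongest decreases were those of late epidermal genes in the same chromosomal cluster, namely CRCT1 (-7.03 ± 0.47), LCE3D (-6.29 ± 0.74), LCE3E (-6.01 ± 0.68) and SPRR2A (-4.90 ± 0.46). The cytidine deaminase gene APOBEC3A fell by 5.12 on the log2 scale, the chemokine gene CXCL3 by 5.07 and the cytokine gene IL24 by 4.90. KLHL11 (-5.52), C11orf96 (-5.50), RAD21-AS1 (-5.04) and RNVU1-18 (-4.94), a variant of the U1 small nuclear RNA, made up the rest of the 12. STON1, CDK14 and GNAO1 were not well above background on either control array, and their hairpin signal was at least 91.4-fold, 51.2-fold and 31.2-fold higher as a mean over both lines, with 2 of 3 GNAO1 probes rising. These bounds need not hold in CAL27 alone. Averaged over probes GNAO1 had 2.46, and with normexp, whose offset shrinks changes of dim genes, STON1, CDK14 and GNAO1 had 3.11, 2.29 and 1.85 and did not pass (adjusted p = 0.094, 0.058 and 0.066). With slide as a block STON1 (adjusted p = 0.076) and GNAO1 (0.0504) did not pass. MPC1L, COX8C and SCARNA2 were not well above background on any hairpin array, and their control signal was at least 125-fold, 69.0-fold and 34.1-fold higher as a mean over both lines. With normexp these 3 had -3.29, -2.60 and -1.68, well short of the bounds.

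**Figure D1:**
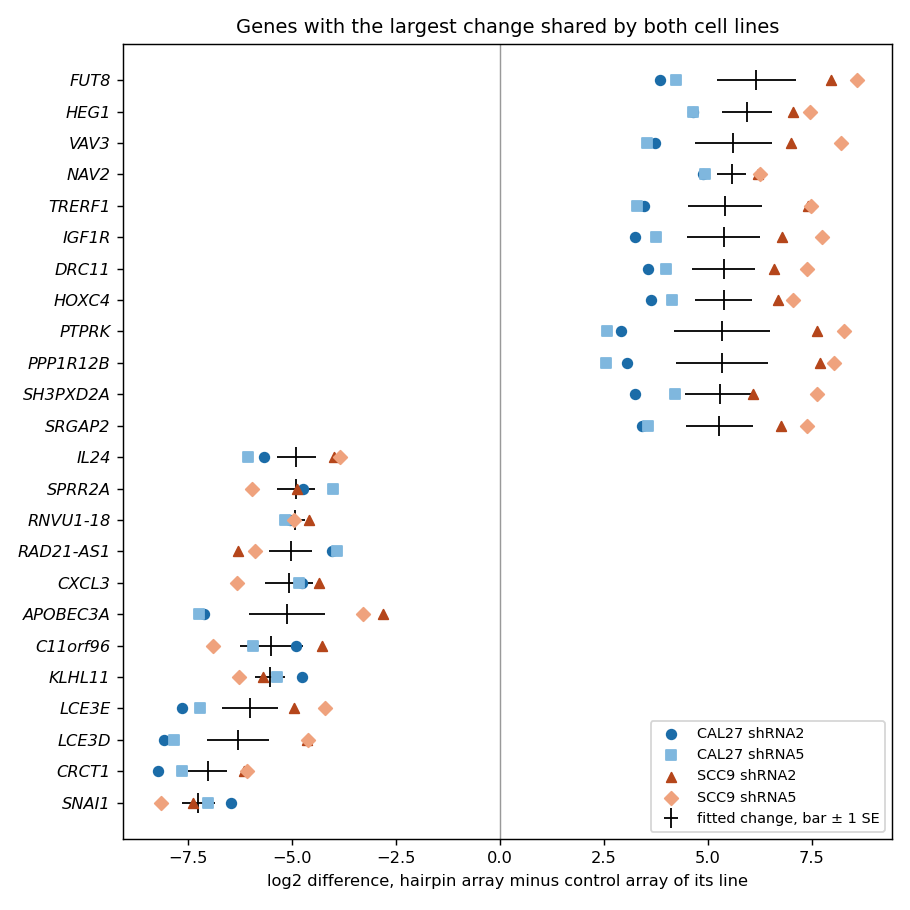
Log2 differences between each hairpin array and the control array of its line for the 12 genes with the largest increase and the 12 with the largest decrease shared by both cell lines, among genes well above background on all 6 arrays. Coloured symbols are single arrays, and the black mark with its bar is the fitted change ± 1 SE. The rule that chose the genes required all 4 differences of a gene to lie on the same side of 0. The fitted changes run from FUT8 at 6.16 to SNAI1 at -7.25.

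The G2 and M phase list had the largest median change of the 35 lists fixed beforehand, 2.47 on the log2 scale. Of 39 measured members of the G2 and M phase list, 32 rose and 0 fell (36 and 0 adjusted over the list alone). Examples were the kinesin gene KIF11 (5.26 ± 0.76), the spindle checkpoint kinase gene BUB1B (4.34 ± 0.43) and the topoisomerase gene TOP2A (3.68 ± 0.36). Of 38 S phase and replication genes, 19 rose and 0 fell (25 and 0 adjusted over the list alone), among them POLA1 (3.08 ± 0.39), GINS1 (2.79 ± 0.30) and RRM1 (2.22 ± 0.28). Of 43 genes of crosslink and break repair, 18 rose and 1 fell (19 and 1 adjusted over the list alone). BRCA1, which acts in homologous recombination and has been linked to LINC01011 in work on cisplatin sensitivity, rose by 3.16 ± 0.55 (adjusted p = 0.019), with differences of 2.70 and 2.25 in CAL27 and 4.60 and 3.10 in SCC9. The Fanconi anaemia gene FANCC rose by 3.60 ± 0.24, CHEK2 by 3.21 ± 0.47 and ATM by 2.54 ± 0.54. ERCC6, which acts in transcription-coupled repair, fell by 2.11 on the log2 scale. The 3 lists passed the set test (limma camera with a preset correlation, adjusted p = 2.7e-17, 7.4e-10 and 0.00011). None of the 35 lists passed with a correlation estimated from the 6 arrays: for these 3, the adjusted p = 0.52 with an estimated correlation. The change also grew with gene length, as given below. Tested genes of 82.5 kb or more had a median change of 1.20 and an upper quartile of 2.36, whatever their function. With the trend with gene length removed, camera with the preset correlation gave adjusted p = 0.015 for the crosslink and break repair list.

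Of 46 measured interferon-stimulated genes, 18 rose and 1 fell (26 and 3 adjusted over the list alone), including TRIM22 (3.90 ± 0.70) and IFIT1 (2.41 ± 0.50). ISG20 fell by 1.57 on the log2 scale. Of 32 hypoxia and glycolysis genes, 16 rose and 1 fell (18 and 1 adjusted over the list alone), among them the kinase gene PDK1 (2.76 ± 0.34), the glucose transporter gene SLC2A1 (2.72 ± 0.30) and CA9 (2.70 ± 0.52). Cholesterol and fatty acid synthesis contributed 12 increases and 0 decreases among 31 genes, the same numbers as adjusted over the list alone, with LSS (2.02 ± 0.36) as an example. The median of this list was 0.76 and 0.96 in CAL27 shRNA2 and shRNA5 and 0.05 and 0.16 in SCC9 shRNA2 and shRNA5, and without the CAL27 control it did not pass (adjusted p = 0.17). The preset-correlation test gave adjusted p = 4.8e-08, 9.1e-07 and 0.00028 for these 3 lists, and each had adjusted p = 0.52 with an estimated correlation. Of 25 genes of platinum transport and detoxification, 6 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.52 with an estimated correlation). The metallothionein gene MT1E rose by 2.41 ± 0.34, and the copper chaperone gene ATOX1 fell by 2.36 on the log2 scale. This list did not pass in the CAL27 arrays alone (adjusted p = 0.097) or without the SCC9 control (adjusted p = 0.067).

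Basal epithelial identity genes and several developmental signalling lists were higher. Of 20 basal squamous genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), including TP63 (3.30 ± 0.60), the master regulator of stratified epithelia, DST (3.63 ± 0.62) and EGFR (3.03 ± 0.57). Of 38 Wnt pathway components 12 rose and 2 fell (14 and 2 adjusted over the list alone), led by TCF7L1 (4.92 ± 0.29). Of 25 Wnt target genes 9 rose and 3 fell (10 and 4 adjusted over the list alone). ZNRF3 rose by 4.21 ± 0.59, whereas AXIN2 fell by 1.21 on the log2 scale. Of 26 Notch genes 7 rose and 1 fell, also adjusted over the list alone, with JAG2 at 4.64 ± 0.40. Of 26 YAP target genes 11 rose and 2 fell (13 and 2 adjusted over the list alone). CCN2, one of the best known YAP targets, went against the list with -4.34 ± 0.50. Of 28 TGF-beta target genes 8 rose and 4 fell (10 and 4 adjusted over the list alone), with SMAD6 at 5.18 ± 0.86. Of 28 mesenchymal genes 8 rose and 2 fell (10 and 3 adjusted over the list alone). CDH2 and LOX rose by 3.01 ± 0.31 and 3.17 ± 0.37, against the fall of SNAI1. In this order, the preset-correlation test gave adjusted p = 8.4e-06, 0.00013, 0.0025, 0.0063, 0.014, 0.012 and 0.012. With an estimated correlation the adjusted p = 0.61 for TGF-beta targets and the adjusted p = 0.52 for the 6 other lists. With the trend with gene length removed, the YAP (adjusted p = 0.25), mesenchymal (0.16) and TGF-beta (0.058) lists did not pass. Without the SCC9 control the Notch (0.073), YAP (0.055), TGF-beta (0.29) and mesenchymal (0.091) lists did not pass, nor in the CAL27 arrays alone (0.052, 0.072, 0.37 and 0.14), where the Wnt target list did not either (0.052).

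The lists that fell were led by the immediate early genes of MAPK signalling, of which 0 of 43 rose and 25 fell (2 and 28 adjusted over the list alone). FOS (-4.48 ± 0.27), FOSB (-4.78 ± 0.50), NR4A1 (-3.91 ± 0.62) and the growth factor gene HBEGF (-4.77 ± 0.57) fell, while EGR1 (-0.40 ± 0.36) did not pass. Of 44 genes of keratinocyte differentiation, 0 rose and 16 fell (0 and 17 adjusted over the list alone), including SPRR3 (-4.53 ± 0.49), SBSN (-4.44 ± 0.26) and KRT6B (-2.82 ± 0.28). Of 32 genes of ribosome biogenesis under MYC, 0 rose and 6 fell, as when adjusted over the list alone, with NOP56 (-1.91 ± 0.33) and ODC1 (-1.98 ± 0.38). Its median was -0.29 and -0.19 in CAL27 shRNA2 and shRNA5 and -1.53 and -1.40 in SCC9 shRNA2 and shRNA5, and it did not pass without the SCC9 control (adjusted p = 0.12) or in the CAL27 arrays alone (adjusted p = 0.10). Keratinocyte differentiation did not pass without the CAL27 control (adjusted p = 0.94). The preset-correlation test gave adjusted p = 8.4e-06, 0.0028 and 0.0078, and with an estimated correlation the adjusted p = 0.52, 0.61 and 0.71. Inflammatory NF-kB genes fell in part, with 3 of 32 higher and 10 lower (3 and 11 adjusted over the list alone). CXCL2 (-3.93 ± 0.65), IL6 (-3.93 ± 0.98) and TNF (-3.28 ± 0.54) fell, while CCL2 rose by 2.55 and the list itself did not pass (adjusted p = 0.096). It passed as lower with the 75th percentile shift (adjusted p = 0.040), slide as a block (0.0045), the CAL27 arrays alone (0.00074), without the SCC9 control (0.024) and without SCC9 shRNA5 (0.029). Of 32 p53 target genes 3 rose and 10 fell (4 and 10 adjusted over the list alone). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had a log2 change of -2.76 ± 0.36, GADD45A of -2.63 ± 0.23 and MDM2 of -1.15 ± 0.22, and DDB2 rose by 2.51. This list did not pass either (adjusted p = 0.20), but passed as lower in the CAL27 arrays alone (0.038) and without the SCC9 control (0.037).

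**Figure D2:**
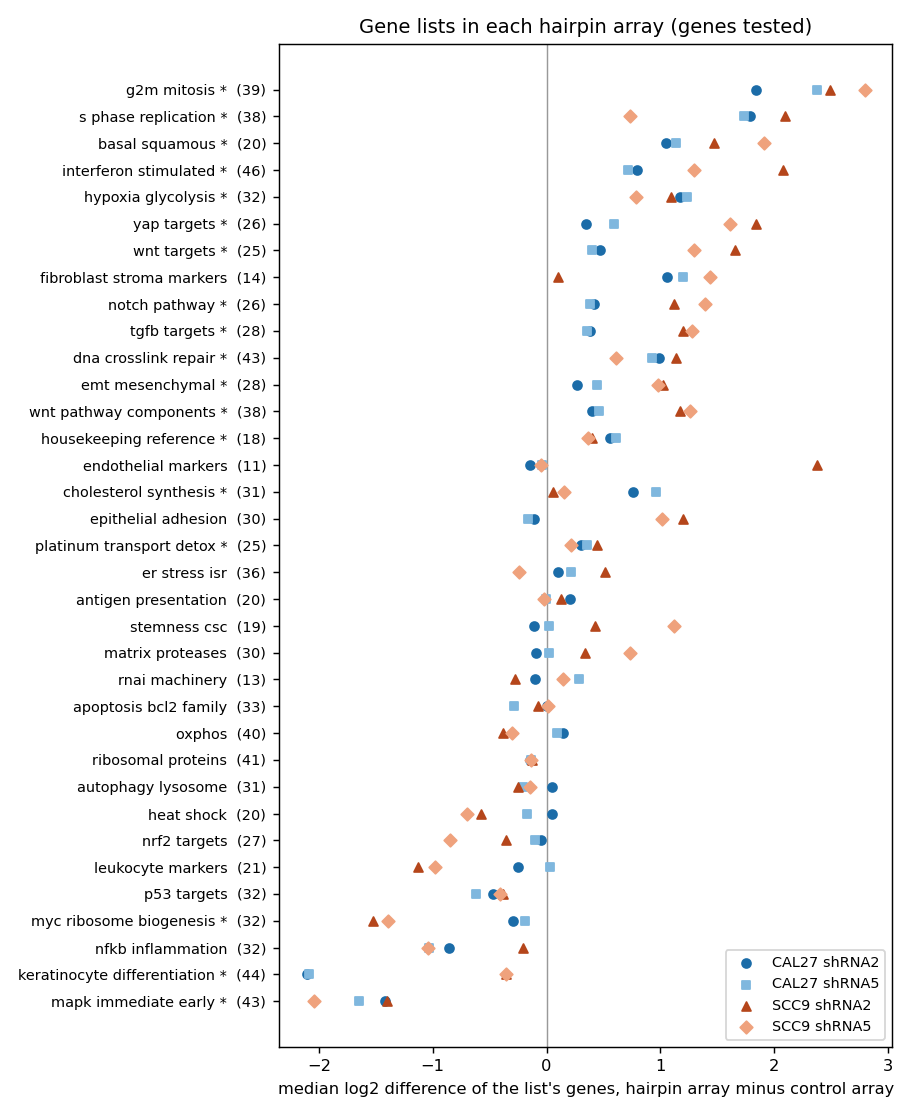
Median log2 difference of the genes of each of the 35 lists in each hairpin array against the control array of its line, with the number of genes tested in parentheses. Each symbol is a single array, and an asterisk marks the 18 lists past the camera test with a preset correlation. The G2 and M phase list (fitted median 2.47) is at the top and the immediate early list (-1.77) at the bottom.

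The other lists did not pass the camera test, apart from the housekeeping reference genes, of which 3 of 18 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.52 with an estimated correlation). YWHAZ rose by 1.21 and POLR2A fell by 1.29; the list's median of 0.55 turned to -0.20 when arrays were scaled by their 75th percentile, where it did not pass (adjusted p = 0.96). Nor did it without the SCC9 control (adjusted p = 0.059) or in the CAL27 arrays alone (adjusted p = 0.083). None of the 41 ribosomal protein genes passed, nor did any when adjusted over the list alone. Their median was -0.13, the largest value was that of RPL3 (0.86 ± 0.28, adjusted p = 0.071), and relative to all genes their sign turned with the 75th percentile scaling and with the normexp background correction. The list passed as lower with that scaling (adjusted p = 7.3e-06) and as higher with the trend with gene length removed (adjusted p = 0.0056). Epithelial adhesion genes went both ways, 5 of 30 up and 6 down (7 and 7 adjusted over the list alone), with CLDN1 at 3.06 ± 0.32 and DSC2 at -2.56 ± 0.31. Genes of the unfolded protein and integrated stress responses also split, 5 of 36 up and 4 down, as when adjusted over the list alone, with SLC7A5 at 2.99 ± 0.24 and ATF3 at -3.75 ± 0.91. Among 33 apoptosis regulators 3 rose and 4 fell (2 and 4 adjusted over the list alone), with PMAIP1 at -3.02 ± 0.45. Autophagy and lysosome genes had 3 increases and 8 decreases among 31, with MAP1LC3B at -1.98 ± 0.26, NRF2 targets 3 and 4 among 27, with SRXN1 at -1.69 ± 0.27, and matrix proteases and their inhibitors 3 and 4 among 30, with SERPINB2 at -4.05 ± 0.42. Each of these 3 lists gave the same numbers adjusted over the list alone. Of 20 heat shock genes 1 rose and 3 fell (1 and 2 adjusted over the list alone), of 19 stemness genes 4 and 3 (5 and 4), of 13 genes of RNA interference 2 and 1 (3 and 3), of 20 antigen presentation genes 1 and 0 (1 and 0) and of 40 oxidative phosphorylation genes 2 and 1 (0 and 0). With the 75th percentile shift the heat shock (adjusted p = 0.019) and oxidative phosphorylation (0.0068) lists passed as lower. Antigen presentation passed as higher with the length trend removed (0.019), and epithelial adhesion as higher without the CAL27 control (0.0060). DROSHA and DICER1, the nucleases of microRNA maturation, rose by 1.72 ± 0.33 and 1.43 ± 0.38. Among markers of cell types foreign to these cultures, 0 of 11 endothelial markers passed, 1 of 21 leukocyte markers fell (CD68, -1.17 ± 0.28, and 0 adjusted over the list alone), and of 14 fibroblast markers 4 rose and 1 fell, as when adjusted over the list alone. The last were led by the complement genes C1S (3.06 ± 0.43) and C1R (2.42 ± 0.32), which epithelial cells also express. The fibroblast list had a median of 0.92 and did not pass (adjusted p = 0.066), but passed with the 75th percentile shift (adjusted p = 0.023), the filter on all 6 arrays (0.027), the authors' table (0.046) and slide as a block (0.013).

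The change followed gene length, taken as the span of the gene in the reference annotation, which was known for all 16757 tested genes with a symbol. The shortest quintile, of up to 7.10 kb, had a median change of -0.51 over the 4 hairpin arrays, and the longest, from 82.5 kb, a median change of 1.20. In the longest quintile 1060 genes rose and 101 fell, against 166 and 717 in the shortest. Spearman's rho between change and length was 0.29 and 0.31 in the CAL27 shRNA2 and shRNA5 arrays and 0.42 and 0.45 in the SCC9 shRNA2 and shRNA5 arrays; these are correlations across genes, which are not independent replicates. The genes that rose had a median length of 69.98 kb, those that fell 13.3 kb and those that did not pass 23.9 kb. Among the 12 leading increases, lengths ran from 39.1 kb (HOXC4) to 776 kb (NAV2), and among the 12 leading decreases the longest was KLHL11 with 16.9 kb. The immediate early list had a median length of 8.29 kb, keratinocyte differentiation 5.55 kb, G2 and M phase 28.5 kb and crosslink repair 44.3 kb.

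**Figure D3:**
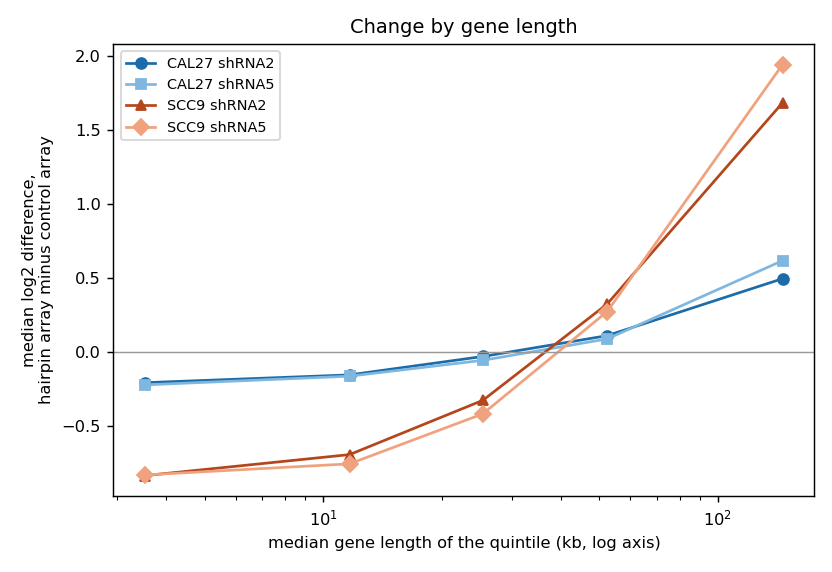
Median log2 difference of each hairpin array against the control array of its line in 5 equal groups of genes ordered by gene length, placed at the median length of each group in kb on a log axis. Each line is a single array and has no error bar. In SCC9 shRNA5 the median rises from -0.83 in the shortest group to 1.94 in the longest, and in CAL27 shRNA2 from -0.21 to 0.50.

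The arrays lay on 2 slides, with the 3 CAL27 arrays and SCC9 shRNA2 on slide 1 and SCC9 control and SCC9 shRNA5 on slide 2. With slide as a block 622 genes were higher and 783 lower, a fit in which the slide term takes up the whole SCC9 shRNA2 array, and 20 lists passed. The comparison within slide 1 is that in CAL27 below, and slide 2 holds 1 pair, SCC9 shRNA5 against its control, which has no test. Leaving out 1 hairpin array at a time gave 1512 genes without CAL27 shRNA2, 622 without CAL27 shRNA5, 1405 without SCC9 shRNA2 and 1664 without SCC9 shRNA5. The count was 13911 without the CAL27 control and 4608 without the SCC9 control, when it rests on the other line.

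Within each line, the question was whether both hairpins changed a gene relative to the lone control, which was assumed to vary like the hairpin arrays. In CAL27, 2262 genes were higher and 2346 lower. TCF7L1, a transcription factor of the Wnt pathway, led the increases with 5.17 ± 0.32 (SE, adjusted p = 0.013), followed by NAV2 (4.91 ± 0.18), FAT2 (4.76 ± 0.45), MATN2 (4.69 ± 0.45) and HEG1 (4.65 ± 0.25). LCE3D (-7.96 ± 0.20), CRCT1 (-7.93 ± 0.30), LCE3E (-7.43 ± 0.40), APOBEC3A (-7.18 ± 0.27) and SNAI1 (-6.75 ± 0.44) led the decreases by the same rank. Keratinocyte differentiation genes had median differences of -2.11 and -2.09 in the CAL27 shRNA2 and shRNA5 arrays, both below every one of 10000 random lists of like expression (percentile 0). In the SCC9 shRNA2 and shRNA5 arrays their medians were -0.36 and -0.36, at percentiles 26.1 and 30.7. The count in CAL27 fell to 0 genes without CAL27 shRNA2 and without CAL27 shRNA5, fits with 1 residual degree of freedom.

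In SCC9, 5458 genes were higher and 8453 lower, 62.1% of those tested. The balance of directions depended on the scaling. Of the genes that passed, 39.2% were higher, and 30.8% with the 75th percentile shift, where the median gene moved from -0.41 to -0.81. Genes with a symbol and well above background on all 6 arrays were again ranked by the smaller of the 2 hairpin differences, and fitted changes are given. AKAP13, an anchoring protein of protein kinase A, came first with 8.94 ± 0.42 (adjusted p = 0.0012). Next by that rank were FNDC3B (8.63 ± 0.28), TULP4 (8.46 ± 0.38), FUT8 (8.29 ± 0.35) and PPP1R12B (7.86 ± 0.31), of which 2 of 4 probes rose in this line. These sizes rest on low values on 1 array, the dim SCC9 control, whose spread the SE does not hold. There the normalized log2 value was 3.31 for AKAP13, against 9.89 to 12.67 on the other arrays, and 3.25 to 3.96 for the others named. Such sizes depend on the background correction, and all of these genes were long, from 244 to 387 kb. SNAI1 (-7.76 ± 0.44), CRCT1 (-6.12 ± 0.30), RAD21-AS1 (-6.09 ± 0.25), LINC00520 (-5.81 ± 0.23) and STX17-DT (-5.78 ± 0.19) led the decreases by the same rank, which is not that of the fitted changes. Across all genes the SD of the differences was 1.94 and 2.04 in the SCC9 shRNA2 and shRNA5 arrays against 1.08 and 1.18 in those of CAL27. The lines share no array, and 1765 genes were higher in both and 1848 lower in both, where independent lists of these sizes would share 551 and 885. The tests in both lines use the same pooled spread for each gene, so a gene with a small spread tends to pass in both. The lists are thus not independent, and part of the excess may come from this. Across genes the differences correlated at r = 0.57 to r = 0.62 between the lines. A further 203 genes passed in both lines in opposite directions.

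**Figure D4:**
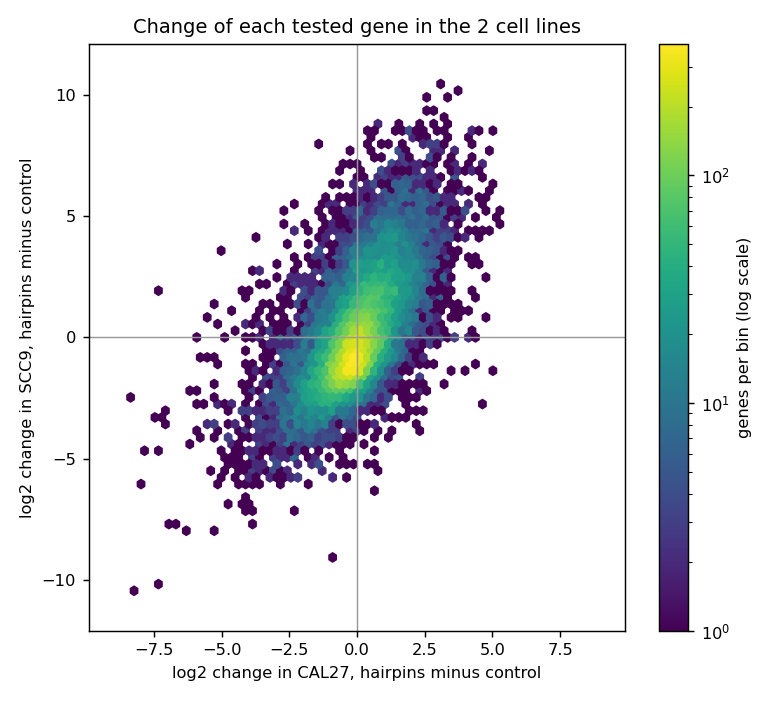
Log2 change of each of the 22415 tested genes in CAL27 (horizontal axis) and SCC9 (vertical axis), both as the mean of the 2 hairpin arrays minus the control, with the number of genes per bin as colour on a log scale. The cloud runs from lower left to upper right and extends farther along the SCC9 axis.

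The effect itself was then compared between the lines. It differed for 5491 genes, 2745 more positive and 2746 more negative in SCC9, with a median gene at -0.30. The directions were less even with normexp (2602 and 3854), the filter on all 6 arrays (2597 and 3896) and the 75th percentile shift (2069 and 2717). For 89.0% of the 5491 genes the change was larger in SCC9. UBD, an interferon-inducible ubiquitin-like modifier, had a difference of effect of 6.05 ± 0.30 (adjusted p = 0.015), since it rose in both SCC9 hairpin arrays (5.99 and 5.75) and hardly moved in CAL27 (-0.13 and -0.24). ALDH1A1, a retinaldehyde dehydrogenase, (5.17 ± 0.28) and the ubiquitin ligase gene ITCH (5.21 ± 0.26) also moved more in SCC9. The sorting receptor gene SORT1 (6.25 ± 0.34) went opposite ways, with -1.01 and -0.79 in CAL27 shRNA2 and shRNA5 and 5.20 and 5.51 in SCC9 shRNA2 and shRNA5. CDKN2A-AS1 (-3.33 ± 0.27), LINC00575 (-3.71 ± 0.30), SPMAP2 (-3.50 ± 0.29) and PPAN-P2RY11 (-3.34 ± 0.28) were lower by more in SCC9. Leaving out CAL27 shRNA2 or CAL27 shRNA5 left 0 genes.

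Each hairpin was also set against the controls of both lines, since a hairpin can have effects apart from its target. No gene passed for shRNA2 or for shRNA5 with 2 residual degrees of freedom (limma), where 6342 and 6728 genes had an unadjusted p under 0.05. Both tests come from 1 fit with the same control arrays and the same spread for each gene, so an overlap of their leading genes is in part built in. The genes with the smallest p were nearly the same for both hairpins. For shRNA2 they were TCF7L1 (4.71 ± 0.35), LOXL2 (4.11 ± 0.32), MATN2 (4.74 ± 0.39) and NAV2 (5.54 ± 0.47) among the higher, and SNAI1 (-6.92 ± 0.41), RNVU1-18 (-4.82 ± 0.33), SBSN (-4.63 ± 0.32) and KLHL11 (-5.23 ± 0.40) among the lower, all at adjusted p = 0.080. For shRNA5 they were TCF7L1 (5.13 ± 0.35), LOXL2 (21.1-fold), MATN2 (5.36 ± 0.39) and the helicase gene PIF1 (4.02 ± 0.31), and SNAI1 (-7.59 ± 0.41), RNVU1-18 (-5.05 ± 0.33), KLHL11 (-5.82 ± 0.40) and PLA2G4D (-4.89 ± 0.34), all at adjusted p = 0.055. These counts moved with the processing: the 75th percentile scaling gave 180 genes for shRNA2 and 1424 for shRNA5, and slide as a block gave 380 and 3130. Leaving out 1 array gave, for shRNA2 and shRNA5, 1875 and 3130 genes without CAL27 shRNA2, 14348 and 14234 without the CAL27 control and 2984 and 2665 without CAL27 shRNA5. It gave 380 and 3130 without SCC9 shRNA2, 4213 and 5362 without the SCC9 control and 2984 and 765 without SCC9 shRNA5. Each of these fits has 1 residual degree of freedom. The hairpins' differences from the same control correlated across genes at r = 0.93 in CAL27 and r = 0.95 in SCC9, where simulated unchanged arrays sharing a control gave r = 0.50 and r = 0.51. The covariances were 1.18 and 3.75 against 0.094 and 0.22 for unchanged arrays. Each line has 1 control, which could not be split, so part of the excess may come from the shared control.

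The hairpins were compared directly as well. No gene passed between shRNA5 and shRNA2 (limma), and 344 had an unadjusted p under 0.05. PIF1 had the smallest p, with 3.52 ± 0.31 and adjusted p = 1, followed among the higher by DENND1A (2.17 ± 0.32), SORCS2 (3.42 ± 0.50) and CDH13 (2.34 ± 0.35). The interleukin gene IL6 (-2.41 ± 0.54), ECM2 (-2.14 ± 0.50), ATF3 (-2.22 ± 0.52, with 2 of 4 probes lower) and DDIT3 (-1.64 ± 0.39), a transcription factor of the integrated stress response, had the smallest p among the lower. The count was 31 without CAL27 shRNA2, 52 without CAL27 shRNA5, 2 without SCC9 shRNA2 and 11 without SCC9 shRNA5.

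The lines themselves were compared with the arm in the model, 3 arrays against 3. SCC9 had higher levels of 1332 genes and lower levels of 1184. AMTN, an enamel protein gene, was higher in SCC9 by 10.28 ± 0.64 (log2, adjusted p = 0.0014) and KRT19, a simple epithelial keratin gene, by 8.19 ± 0.68, together with its pseudogene KRT19P2 (8.01 ± 0.64), whose probe may not be told apart from it. CYB5A (7.43 ± 0.26), the fibroblast activation protease gene FAP (7.38 ± 0.40), MYADM (6.96 ± 0.50), TFPI2 (6.82 ± 0.53), FBLN2 (6.57 ± 0.65), TCIM (6.54 ± 1.15) and SALL4 (6.32 ± 0.22) followed. SLC20A2, SMIM19, ZNF260 and KRABD1 were on in the 3 SCC9 arrays and not well above background in any of CAL27, at least 416-fold, 373-fold, 316-fold and 264-fold higher. Interferon-stimulated genes separated the lines most among the lists, since 34 of 46 were lower in SCC9 and 0 were higher, with BST2 (-7.90 ± 0.35) and CMPK2 (-7.57 ± 0.43) as the leading genes. Of 31 cholesterol synthesis genes 19 were lower in SCC9 and 0 higher. These 2 lists had adjusted p = 2.1e-26 and 7.2e-15 with the preset correlation, and no list passed with an estimated correlation, where the smallest adjusted p = 0.54. SPRR1A (-6.34 ± 0.38), SLCO4A1 (-5.83 ± 0.69), the growth factor genes PTN (-5.78 ± 0.24) and NRG1 (-5.61 ± 0.32), SLC15A3 (-5.56 ± 0.41), GNB4 (-5.53 ± 0.28), PTX3 (-5.48 ± 0.47) and NLRP2 (-5.46 ± 0.36) were also lower in SCC9. DDX43, IRX1, CCN6 and CEP15 were well above background in the 3 CAL27 arrays and in none of SCC9, at least 344-fold, 278-fold, 277-fold and 159-fold higher in CAL27. These bounds, and those of SLC20A2, SMIM19, ZNF260 and KRABD1, hold only for the main background correction. The bounds given for hairpins against controls were not reached with normexp, and the bounds between lines were not checked with it. With slide as a block 177 genes differed and without the arm term 640. The count was 541 without CAL27 shRNA2, 613 without CAL27 shRNA5, 876 without SCC9 shRNA2 and 721 without SCC9 shRNA5, and 6483 without either control array.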

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

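The test of the slide in the last paragraph was chosen after the result was seen. The knockdown effect differed between the lines for 5491 genes (limma, adjusted p under 0.05 for the difference SCC9 minus CAL27). Named by the rule, UBD (6.05), ITCH (5.21), ALDH1A1 (5.17) and SORT1 (6.25) were more positive in SCC9 on the log2 scale, and CDKN2A-AS1 (-3.33), LINC00575 (-3.71), SPMAP2 (-3.50) and PPAN-P2RY11 (-3.34) more negative.

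The difference between lines also passed for 11 gene lists with the preset correlation of camera, and for none with an estimated correlation (smallest adjusted p = 0.52). The median difference, SCC9 minus CAL27, was 1.59 for keratinocyte differentiation, whose genes were lower in CAL27 hairpin arrays by far more than in those of SCC9. It was 1.21 for basal squamous genes, 0.999 for epithelial adhesion, 0.97 for TGF-beta targets, 0.88 for interferon-stimulated genes, 0.83 for YAP targets, 0.67 for Wnt components, 0.66 for matrix proteases and 0.60 for G2 and M phase genes. It was -0.96 for ribosome biogenesis genes under MYC and -0.60 for oxidative phosphorylation.

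Most of these genes moved farther in SCC9, whose control array is alone on its side of the comparison and was the dimmest of the 6. A difference between slides does not account for the larger change, since the difference within slide 2 (SCC9 shRNA5) had an SD 1.05 times that of the difference between slides (SCC9 shRNA2). Noise of genes near background does not account for all of it. The SD in SCC9 was still 1.59 times that in CAL27 among the brightest decile of genes, against 1.77 times over all genes. That decile was taken by the mean level over the 6 arrays and can hold genes dim only on the SCC9 control. The test therefore cannot exclude a cause of that array's low signal that also acts on bright genes. CAL27 RNA on the SCC9 control array is argued against by 200 genes that separate the lines in the hairpin arrays and move little in CAL27, of which 91.5% differed the same way between the control arrays. Over all genes, however, the SCC9 control correlated more with the CAL27 control (r = 0.886) than with the SCC9 hairpin arrays (r = 0.845 and r = 0.830). What stays open is the cause of the low signal of the SCC9 control array, the state of that 1 culture or RNA sample, including its dose and RNA quality, and a true difference between the lines. No second SCC9 control was analysed here.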

How the results depend on the processing

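Normexp on the median signals, the removal of the length trend and the CAL27 arrays alone were chosen after seeing the data; the planned normexp on mean signals could not be run, since the files carry median spot signals and no mean spot signals. Of the counts of genes and lists under an alternative, 89 stayed within 1.5 times the main count and 45 did not. Without the length trend 4440 of 16757 genes passed between hairpins and controls and 17 lists; with the CAL27 arrays alone 6528 genes and 12 lists. The 75th percentile shift moved the median gene of that comparison from -0.23 to -0.46 and the lists passing from 15 up and 3 down to 15 up and 7 down. The 30 genes named for hairpins against controls kept their direction in all 504 values, with 52 of them no longer past the threshold; over all 504 the adjusted p ran from 0.0012 to 0.16.

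Counts that moved farther were as follows, and the cause was not tested unless given. For shRNA5 against control, 0 genes became 1424 with the 75th percentile shift, 786 with normexp, 1084 with the filter on all 6 arrays, 741 with the authors' table and 1388 with trend and robust settings; for shRNA2 the 75th percentile shift gave 180. Slide as a block leaves fewer residual degrees of freedom and takes up the SCC9 shRNA2 array: it gave 1405 genes for hairpins against controls, 380 for shRNA2, 3130 for shRNA5, 2 for shRNA5 against shRNA2 and 177 for SCC9 against CAL27. Without the cell line term (no replicate block) 2037 genes passed between hairpins and controls, since line differences then enter the spread, and without the arm term 640 passed between the lines. No paired analysis by replicate number was possible because the labels give none. With an estimated correlation 0 lists passed, and with fry 13.

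Leaving out 1 array changed the counts from 622 to 13911 for hairpins against controls, 0 to 6528 in CAL27, 10432 to 14363 in SCC9, 0 to 7221 for the difference between lines, 380 to 14348 for shRNA2, 765 to 14234 for shRNA5, 0 to 52 for shRNA5 against shRNA2, 541 to 6483 for SCC9 against CAL27, and 13 to 20 lists. The highest counts for hairpins against controls, shRNA2 and shRNA5 came without the CAL27 control. Signal over background limits genes below background on some arrays: with no filter 4373 of 27646 genes passed between hairpins and controls.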

Other observations

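The test of a weaker block of transcription was written after the result was seen. The interferon-stimulated list had a median difference between SCC9 and CAL27 of -2.98 on the log2 scale (adjusted p = 0.54 with an estimated correlation). Between hairpin and control arrays (adjusted p = 0.52 with an estimated correlation) its medians were 0.80 and 0.72 in CAL27 shRNA2 and shRNA5 and 2.07 and 1.299 in SCC9 shRNA2 and shRNA5.

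The change between hairpin and control arrays grew with gene length. Probe brightness does not account for it, since the median rho within deciles of brightness was 0.469 and the lowest 0.257; nor does the slide, since rho was 0.288 or more in the CAL27 arrays, all on 1 slide; nor does quantile normalization, with rho = 0.437 under the 75th percentile shift. A candidate explanation, found from these same data, is a weaker block of transcription of long genes in the hairpin arrays, as platinum adducts may stall polymerase more often in long genes. The smallest rho of the 4 hairpin arrays, 0.288, restates the pattern, so it is no independent test and the explanation stays open. Whether the arms had the same effective cisplatin exposure, the RNA quality of the control samples and an effect of LINC01011 itself were not tested and stay open.

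Gene lists moved between hairpin and control arrays, and the 6 with the smallest p in these data were placed among random lists matched on gene length. The G2 and M phase, S phase, interferon and hypoxia lists were at percentile 100, basal squamous genes at 99.9 and immediate early genes at 0. Random lists hold unrelated genes, whereas the estimated correlation within these 6 lists ran from 0.065 (hypoxia) to 0.77 (S phase). Correlated genes reach extreme percentiles more easily, and housekeeping genes were at 99.5, so the percentiles cannot exclude gene length. With the length trend removed, all 6 lists still passed camera with the preset correlation. The other lists past the camera test also lay above 99 or, for keratinocyte differentiation (0) and ribosome biogenesis (0.20), at the low end, apart from platinum transport at 94.2. None of these lists passed with an estimated correlation (smallest adjusted p = 0.52), and with the length trend removed the YAP (adjusted p = 0.25), mesenchymal (0.16) and TGF-beta (0.058) lists did not pass. A difference in drug exposure or growth between the cultures and an effect of the hairpins stay open, and no biological explanation was tested.

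Regroupings of the arrays were too few for a share under 0.05. Between the lines 2516 genes passed in 1 of 10 splits of 3 against 3 arrays, where the highest other count was 1. Between hairpins and controls 5706 passed in 1 of 9 choices of a control per line, where the highest other count was 0.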
